A study of Cryptomeria japonica with 80 samples.

How the data were processed

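The libraries were total RNA of cedar shoots, labelled with Cy3 and hybridised to a custom Agilent array, 1 array per library, per the labels. Per the labels' protocols, RNA of the annual series was extracted with a plant RNA kit, and RNA of the chamber cuttings by LiCl precipitation followed by the same kit, so the annual and chamber libraries differ in extraction and were never compared directly. Per the submitters' processing notes, the scans were read with Agilent Feature Extraction 11.5.1.1. The scanner files hold spot intensity per the file headers, as a signal that was background-subtracted and spatially detrended within each array, beside the raw median signal and background. The deposited table of all libraries holds log2 values. Its scaling is not given in the sources used here, but was settled from the values: each probe's median over the 80 arrays is 0, and the table matched log2 intensity scaled to each array's 75th percentile and centred by probe, with r = 0.999983 and a slope of 1.00 over 22194 probes. Replicate 3 of every annual date was deposited separately and scanned in 2018 on 2 slides, whereas replicates 1 and 2 were scanned from 2013 to 2015. No later step of the authors is described.

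The scanner files were analysed with R 4.3.3, limma 3.58.1, statmod 1.5.0 and the data.table package, version 1.17.8. Each probe had 2 or 3 spots, 61657 spots in all, which were averaged on the log2 scale. Spots that Feature Extraction marked as outliers were left out unless all spots of a probe were marked, and 1319 control spots were set aside. The log2 of the array's 75th percentile was subtracted from each value. A probe was called well above background by the scanner software's own mark, and a probe was tested when it was well above background on every array of at least 1 group. This kept 19572 probes in the annual series, 18630 in experiment 1 and 19753 in experiment 2. The share of probes well above background ran from 70.8% to 92.3%, 75.7% to 90.4% and 85.9% to 88.7% of probes per array, and no probe was saturated. For arrays, the number of libraries, 2 or 3 per group, limits the precision.

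Groups followed the labels. Each experiment was fitted with limma with a mean per group, the code at the end of each sample title as a random block, empirical Bayes moderation and a Benjamini-Hochberg adjusted p of 0.05. The codes recur between groups and their meaning is not given, and the consensus correlations within codes were -0.06, 0.22 and 0.02. The comparisons, the dates that form winter and summer, the days that are averaged and most of the other settings tried were chosen before the data were examined. The winter index, the probe groups by date of highest mean, the correlations with date profiles, the letter classes of probe names and the alternatives with E1A spike-ins, array brightness and without dim libraries were chosen after the data were seen. Differences in the index and in brightness were tested with two-sided exact permutation of libraries within days, 10 tests in the family. The same 10 were tested with the title codes as units, each code's values averaged after the mean of each day was subtracted, a test chosen after the data were seen.

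The probes named in the text followed a rule. With no gene names, they are the 2 probes with the largest rise and the 2 with the largest decrease in each of the 3 main comparisons, among called probes whose higher group was well above background in all its libraries and whose direction was the same at each matched day or, for the season, in every winter against every summer library. None of the probe names matched the reference table, 0 in all, so the gene lists fixed beforehand could not be used. Where no library of the dim group was well above background, a lower bound on the fold was computed against the lowest level called well above background on each of its arrays.

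The procedure was tested on simulated data with 50 changed probes at each of 4 sizes. Of the changes of 1 log2 unit, 38, 45 and 49 of 50 were recovered in the annual series, experiment 1 and experiment 2, of those of -1, 35, 44 and 46, and of those of 0.5, 16, 37 and 36. False calls were 14 of 149 (9.40%), 5 of 179 (2.79%) and 5 of 186 (2.69%), so false calls in the annual series ran above the intended rate in that simulation. The simulated noise was independent between libraries, with no effect of slide, code or brightness. Few of the probes were changed, whereas most were called in the main comparisons of the data, so these rates need not carry over. Alternatives covered quantile normalization, normexp background correction with an offset of 50 followed by quantile normalization, the deposited values, no filter, a filter on 50% of arrays, no block, a replicate block, a slide block, a minimum fold of 2, other dates and days, and each library left out. Normexp used the raw median signal because the files hold no mean signal. Leaving out a chamber library leaves its group with 1 library, which is then assumed to vary like the other groups.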

Results

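Transcript levels were measured in shoots of Japanese cedar, an evergreen conifer, on 80 single-colour microarrays with 22194 cedar probes. The annual series held 36 libraries from cuttings of a single clone grown in natural conditions, collected on 12 dates from June 2013 to June 2014 with 3 libraries per date. Experiment 1 held 22 libraries from potted cuttings kept at 25 °C in short days, with 8 h of light and 16 h of dark, or in long days, with 16 h of light and 8 h of dark. Experiment 2 held 22 libraries from cuttings kept in long days at 15 °C or 25 °C. Each chamber group had 2 libraries. Experiment 1 was sampled on days 0, 7, 21, 35, 49 and 70 after transfer, and experiment 2 on days 0, 7, 21, 42, 63 and 90. The 75th percentile of probe intensity lay between 537 and 2471 in the annual series, between 728 and 1779 in experiment 1 and between 1346 and 2315 in experiment 2. Correlations between libraries of 1 group ran from 0.900, in May 2014, to 0.996 in the annual series, from 0.970 to 0.991 in experiment 1 and from 0.980 to 0.994 in experiment 2. Nothing beyond the labels says whether libraries share plants, so p-values measure the spread between these samples. Probes carry identifiers of assembled cedar sequences, which no source used here pairs with gene names, so probes are described by identifier and by the seasonal group they belong to.

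The annual series asked how the shoot transcriptome changes through a year. Winter shoots, the mean of December, January and February, differed from summer shoots, the mean of June 2013, August 2013 and June 2014, in most of the 19572 probes tested. At adjusted p 0.05 in limma, 7225 probes were higher and 6743 were lower in winter, and 3374 and 4071 of them differed by at least 2-fold. The 9 libraries of each season came from 3 dates. The SE and p of this comparison therefore measure the spread between libraries of 1 date, not that between dates or years. The largest rises were in isotig01668, by 15.80 on the log2 scale (SE 0.47, n = 9 and 9, limma adjusted p = 4.72e-21), and isotig01666, by 15.76 (SE 0.45). The largest decreases were in isotig07147, which fell by 14.51 (SE 0.79), and isotig07148, which fell by 14.30 (SE 0.75). In their dim season, the first pair was well above background in 1 of 9 libraries each and the second pair in 2 of 9, so the size and order of these changes depend on how background was removed. Replicate 3 of January is 1 of those 2 libraries, and there 14 of 25 negative control probes carried the same mark.

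The turn towards winter was gradual for these probes. The scaled log2 level of isotig01668 was -8.72 ± 1.09 (SD, n = 3) in August, -1.14 ± 1.15 at the end of September and 6.03 ± 0.93 in October, stayed between 7.05 and 7.64 from November to March, and was -1.34 ± 0.84 in April. isotig07147 took the opposite course, from 6.19 ± 0.55 in August to -8.25 ± 1.27 in December and 2.39 ± 0.72 in April. Across the year, 14998 probes (76.6%) differed between dates in limma's moderated F-test. Of the 12506 among them whose date means spanned at least 1 log2 unit, 4223 (33.8%) were highest from December to February, 4035 (32.3%) in June or August, and 1356 (10.8%) in October or November. December alone held the highest mean of 2529 probes.

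A winter index summarised each library as the mean log2 level of 2955 probes at least 2-fold higher in winter minus that of 3929 probes at least 2-fold lower. These are fewer than the 3374 and 4071 probes called at that size, so the index and the shares drawn from it hold for its own probes only. The loss was larger among winter-higher than among winter-lower probes. How the probes left out behaved in the chambers is not part of these shares, which could be lower or higher with them. The probes of the index were chosen on the annual libraries, so its course there is descriptive. It was -1.43 ± 0.13 (SD, n = 3) in June 2013, 0.10 ± 0.24 at the end of September, 2.62 ± 0.08 in November, 4.18 ± 0.25 in December, 2.42 ± 0.11 in March, 0.25 ± 0.13 in April and -1.49 ± 0.04 in June 2014. The widest changes between neighbouring dates were those from November to December, with 5727 probes, and from March to April, with 5604. The other 9 intervals had 342 to 2903 probes, and each of these counts moved by more than 1.5 times when some single library was left out. Intervals differed in length, and no count was adjusted for it. The interval from 5 August to 30 September had 2296 probes, and the shorter one from 21 February to 11 March had 342. From April to May there were 2579 probes, which became 7877 without replicate 3 of May, 1002 without replicate 2 of May, 1261 without replicate 1 of May, 1655 without replicate 2 of April and 1484 without replicate 3 of April. Without replicate 3 at every date, that interval had the highest count, 6713, but it had 743 without the 7 dim libraries, which left replicate 3 alone for May, 1052 with slide as a block and 109 with slide as a block and spike-in scaling together.

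**Figure D1:**
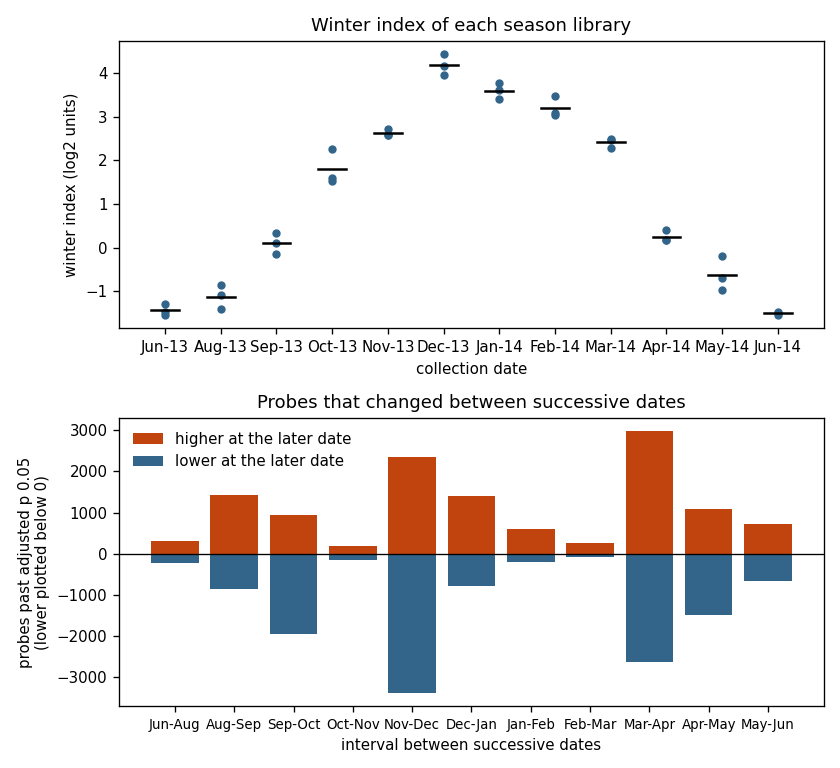
Top, winter index of each annual library (points, n = 3 per date, log2 units) with the mean of each date (bars), which climbs from -1.43 in June 2013 to 4.18 in December and returns to -1.49 in June 2014. Bottom, number of probes higher (above 0) or lower (below 0) at the later of 2 neighbouring dates at adjusted p 0.05, with 5727 probes from November to December and 5604 from March to April.

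June 2013 and June 2014, a year apart, differed in 15 probes at adjusted p 0.05 in limma, 3 of them higher in 2014, and 1819 probes had an unadjusted p under 0.05. This small count rested on single libraries. It was 0 without replicate 2 of June 2013 or without replicate 1 or 3 of June 2014, 1 without replicate 1 of June 2013, and 3 without replicate 2 of June 2014. It was 9 without replicate 3 of August, replicate 1 of November or replicate 2 of February, March or April, 23 without replicate 2 of September and 38 without replicate 3 of May.

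Winter and summer libraries could be compared within 2 slides. The probe differences within slide 13, with 2 libraries of each season, and within slide 16, with 3 winter and 2 summer libraries, share no library and correlated at r = 0.933. Their correlations with the pooled differences, of which these libraries are a part, were 0.961 and 0.989. Probes are not independent replicates in these or any later correlations across probes. The winter split depended on the scaling. With levels taken relative to the E1A spike-in RNA and slide as a block, 5285 probes were higher and 3676 lower, and the median difference of all probes was 0.38 log2, against 0.06 in the 75th-percentile scaling. The date counts then moved as well, to 6080 probes for any date, 1043 from November to December and 2572 from March to April.

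Experiment 1 asked how day length changes shoot transcripts at a constant 25 °C. Averaged over days 21 to 70, isotig18096 was 9.91 log2 units higher in short days than in long days (SE 0.43, n = 8 and 8, limma adjusted p = 6.16e-09) and isotig03405 was 8.56 higher (SE 0.52). In short days isotig16144 fell by 5.64 (SE 0.24) and isotig11093 fell by 5.29 (SE 0.49). In their dim arm, isotig18096 was well above background in 1 of 8 libraries, isotig03405 and isotig11093 in 2 of 8 and isotig16144 in 6 of 8, so the size and order of these differences depend on how background was removed. For isotig03405 the long-day level fell, from -0.85 ± 1.03 (SD, n = 2) at day 0 to -7.88 ± 0.07 at day 70, while in short days it was -0.51 ± 1.63 at day 7 and 1.76 ± 0.50 at day 70. For isotig18096 and isotig16144 the arms lay apart at day 7 and farther apart at day 70. In short days isotig18096 went from -0.62 ± 0.00 (SD, n = 2) at day 7 to 4.99 ± 0.31 at day 70, while in long days it was -6.98 ± 0.71 and -6.60 ± 0.58. isotig16144 went from -1.61 ± 0.15 to -5.57 ± 0.53 in short days and from 2.12 ± 0.00 to 1.09 ± 0.06 in long days. Of the main winter probes, isotig01668 was not well above background in any library up to day 35 of short days and reached 1.83 ± 0.62 at day 70, whereas isotig07147 was 5.33 ± 0.01 at day 21, 4.09 ± 1.47 at day 35 and -4.02 ± 0.17 at day 70 in short days, against 6.17 ± 0.28, 6.37 ± 0.16 and 4.98 ± 0.98 in long days.

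Of 18630 probes tested, 5521 were higher and 5114 lower in short days at adjusted p 0.05, and 821 and 1253 differed by at least 2-fold. The number of responding probes was 563 at day 7 and 7531 at day 70. The change of the effect with time was tested directly, as the effect at days 49 and 70 minus that at day 7, and differed in 3507 probes. The day 7 count was 244 and 143 without replicates 1 and 2 of long days at day 7, and 213 and 277 without replicates 1 and 2 of short days at day 7. The day 70 count was 4837 without replicate 2 of long days at day 70. The count for the change with time was 1356 without replicate 2 of long days at day 7 and 2074 without replicate 1 of short days at day 7.

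Short-day arrays were dimmer. Their 75th percentile lay 0.70 log2 units below that of long-day arrays (mean difference -0.703, lower on 4 of 4 days, exact permutation of libraries p = 0.00309, adjusted 0.00441), and relative to the E1A spike-ins the difference was -0.857 (exact permutation of libraries p = 0.00154, adjusted 0.00257). With title codes as the units, 4 per arm, the exact permutation p was 0.0286 for both, the smallest that 70 arrangements allow (adjusted 0.0409). The split into higher and lower probes therefore depended on the scaling. Relative to the spike-ins with slide as a block, 605 probes were higher and 16244 lower in short days, 3.59% higher among those called against 51.9% in the 75th-percentile scaling, and the median difference of all probes was -0.84 log2, against 0.02. The day 7, day 70 and change-with-time counts were then 105, 12859 and 8411. All directions given for probe groups in short days are relative to the array's 75th percentile, and the 4 probes named for short days kept their direction under both scalings. With array brightness as a covariate, 2068 probes were higher and 2153 lower, 3905 responded at day 70, and the change with time was called in 1144. The short-day effects within slides 8 and 10, which share no library, correlated at r = 0.933. Both held days 35 to 70. The effect within slide 15, from days 7 and 21, correlated with theirs at 0.668 and 0.611, and that within slide 9, from day 7 only, correlated with those of slides 8, 10 and 15 at 0.259, 0.349 and 0.417.

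Experiment 2 asked how temperature changes shoot transcripts in long days. Averaged over days 21 to 90, isotig18088 was 7.60 log2 units higher at 15 °C than at 25 °C (SE 0.90, n = 8 and 8, limma adjusted p = 9.5e-06) and isotig18234 was 7.51 higher (SE 0.80). At 25 °C they were well above background in 1 of 8 and 3 of 8 libraries, so the size and order of these differences depend on how background was removed. The 25 °C levels fell, from -4.15 ± 1.99 (SD, n = 2) at day 0 to -9.12 ± 0.09 at day 90 for isotig18088 and from -3.15 ± 0.89 to -8.99 ± 0.31 for isotig18234, while at 15 °C the levels at day 90 were 0.26 ± 1.03 and 0.21 ± 0.47. The signal of isotig03840 fell by 7.19 (SE 0.19) and was well above background in 0 of 8 libraries at 15 °C, so it was at least 39.8-fold lower. isotig20107 fell by 6.43 (SE 0.29), was also well above background in 0 of 8 libraries, and was at least 45.4-fold lower. isotig03840 was already below that mark in both libraries at day 7, with -8.32 ± 1.03 (SD, n = 2) at 15 °C against -2.46 ± 0.11 at 25 °C. In the annual series isotig03840 was highest in August, at -0.29 ± 0.79 (n = 3), and was not well above background in any library from October to December. isotig20107 was also highest in August, at 1.04 ± 1.13 (n = 3), and was lowest in November, at -6.37 ± 0.31. From December to February, however, isotig20107 was well above background in every library, with date means between -3.11 and -1.74. Its winter difference was -1.07 (SE 0.46, limma adjusted p = 0.0392), against -5.22 (SE 0.48) for isotig03840. The winter probe isotig07147 did not pass the test between temperatures, with a difference of 0.15 (SE 0.08, limma adjusted p = 0.14).

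Of 19753 probes tested, 5362 were higher and 6043 lower at 15 °C, and 672 and 351 differed by at least 2-fold. The temperature response was broad from the start, with 3475 probes at day 7 and 7535 at day 90. The effect at days 63 and 90 differed from that at day 7 in 1 probe in limma, with 2265 at an unadjusted p under 0.05. This count was 81 without replicate 2 of 25 °C at day 63, 51 without replicate 1 of 15 °C at day 7 and 2 without either replicate of day 0. It was 0 without replicate 1 of 25 °C at day 7 or 63, either replicate of 25 °C at day 21, 42 or 90, replicate 2 of 15 °C at day 7 or 63, or either replicate of 15 °C at day 42 or 90. The day 7 count was 2102 and 1694 without replicates 1 and 2 of 25 °C at day 7 and 2148 without replicate 2 of 15 °C at day 7. The day 90 count was 4707 without replicate 2 of 15 °C at day 90. Array brightness differed by 0.073 log2 between temperatures (exact permutation p = 0.483). Relative to the spike-ins with slide as a block, 4115 probes were higher and 4015 lower, with 1533 at day 7 and 4798 at day 90. The effects within slides 11, 12 and 14 correlated with each other at r = 0.863, 0.767 and 0.847. The effect within slide 15, from day 7 only, correlated with theirs at 0.685, 0.592 and 0.433.

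**Figure D2:**
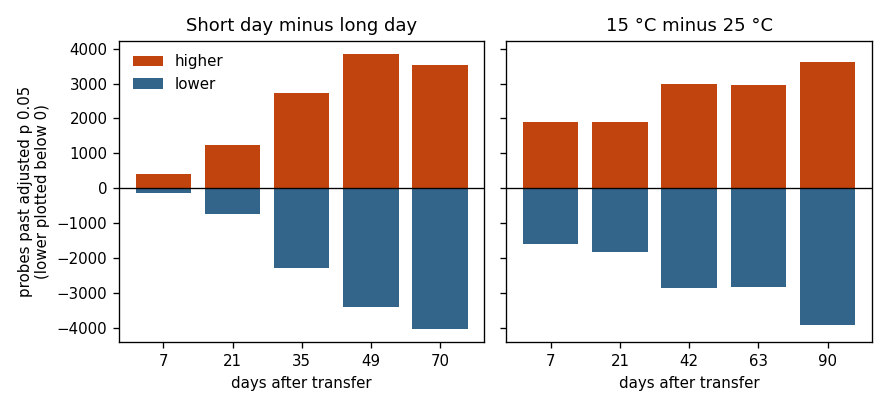
Number of probes higher (above 0) or lower (below 0) at adjusted p 0.05 on each sampling day, for short minus long days (left) and 15 °C minus 25 °C (right), n = 2 and 2 libraries per day. The short-day count goes from 563 at day 7 to 7531 at day 70, and the 15 °C count from 3475 at day 7 to 7535 at day 90.

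The chamber responses were then set beside the winter response, which shares no library with them. Short days moved the winter index up at every sampled day, from -0.96 ± 0.07 (SD, n = 2) at day 7 to 0.91 ± 0.08 at day 70, against -1.35 ± 0.09 and -0.59 ± 0.15 in long days. Over days 21 to 70 the difference was 0.97 log2 units, 19.3% of the winter-minus-summer difference of 5.00, and higher on 4 of 4 days (two-sided exact permutation of libraries within days, p = 0.00154, the smallest the 1296 arrangements allow, adjusted 0.00257 over 10 tests). That test takes libraries as independent, although title codes recur between days. With the codes as the units, 4 per arm, the difference was 1.03 (two-sided exact permutation p = 0.0286, the smallest that 70 arrangements allow, adjusted 0.0409 over 10 tests). At 15 °C the index was higher by 0.56 on 4 of 4 days (exact permutation of libraries p = 0.00154, adjusted 0.00257), 11.1% of the seasonal difference. With 5 codes per arm it was 0.48 (exact permutation p = 0.00794, the smallest that 252 arrangements allow, adjusted 0.0397). The winter-higher part of the index rose by 0.41 in short days and by 0.41 at 15 °C (exact permutation p = 0.00154 each by library, 0.0286 and 0.00794 by code). The winter-lower part fell by 0.55 in short days (exact permutation p = 0.00154 by library, 0.0286 by code), while at 15 °C the difference was -0.15, lower on 3 of 4 days, and missed the threshold after adjustment (exact permutation p = 0.0401 by library, adjusted 0.0501, and 0.214 by code, adjusted 0.268). Unlike the index itself, its parts depend on the scaling. Relative to the spike-ins both parts fell in short days, by 0.45 and 1.41, whereas at 15 °C the differences were 0.41 and -0.14.

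**Figure D3:**
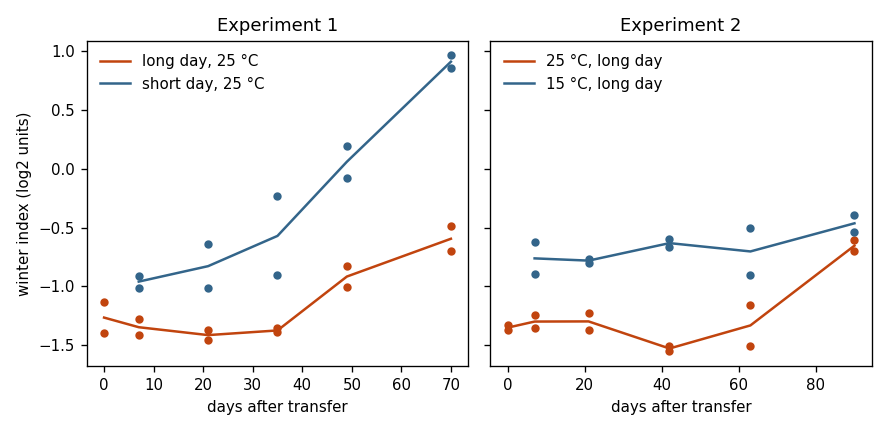
Winter index (log2 units) of each library (points) and mean of each group (lines, n = 2) against days after transfer in experiment 1 (left) and experiment 2 (right). The short-day line climbs from -0.96 at day 7 to 0.91 at day 70, and both constant arms end higher than they began, at -0.59 in long days and -0.65 at 25 °C.

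Probe by probe, the winter and short-day responses correlated at r = 0.531 (Spearman 0.422, jackknife SE 0.049 over libraries, 18540 probes). Among winter-higher probes, 2800 were also higher in short days against 2004 expected for independent calls, and among winter-lower probes 3184 were also lower against 1804 expected. The correlation was 0.334 at day 7 and 0.612 at day 70, and 0.441 with array brightness as a covariate. The winter and 15 °C responses correlated at r = 0.314 (Spearman 0.322, SE 0.061, 19258 probes), with 3201 probes higher in both against 1939 expected and 2733 lower in both against 2060 expected. By day this correlation was 0.350, 0.317, 0.473, 0.329 and, at day 90, 0.038. From day 63 to day 90 the winter index of the 25 °C arm, against which 15 °C is measured, went from -1.33 ± 0.24 (SD, n = 2) to -0.65 ± 0.07. That of the 15 °C arm went from -0.70 ± 0.28 to -0.46 ± 0.10. Of winter-higher probes measured in all experiments, 21.7% were higher under both treatments, 14.2% were called higher in short days with no call at 15 °C, and 17.6% the reverse. Among probes with no winter call these shares were 7.86%, 13.7% and 8.76%, so that for short days alone was much the same. Of winter-lower probes, 20.0% were lower under both, 22.3% were called lower in short days with no call at 15 °C, and 14.5% the reverse. Among probes with no winter call these shares were 7.19%, 7.71% and 19.5%, so calls lower at 15 °C alone were not more frequent among winter-lower probes. Calls in opposite directions were also found: 5.58% of winter-higher probes were higher in short days and lower at 15 °C and 6.16% the reverse, and 6.27% of winter-lower probes were lower in short days and higher at 15 °C and 6.49% the reverse. Among probes with no winter call, 9.67% were higher in short days and lower at 15 °C and 3.76% the reverse. The difference between the treatments was not tested for single probes. Single probes also went against the season. isotig03405, higher in short days, fell by 4.69 in winter (SE 1.02, limma adjusted p = 0.000201), and isotig11093, lower in short days, was 5.59 higher in winter (SE 0.40) and 2.74 higher at 15 °C (SE 0.27). isotig18096 was higher in winter, by 8.44, in short days, by 9.91, and at 15 °C, by 6.05.

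The responses also lay differently against the calendar, a difference that was not tested. The short-day effect correlated most with the November profile, at r = 0.593, and the October profile, at 0.533, and least with June 2013, at -0.658. The 15 °C effect correlated least with August, at -0.474, while its values from November to March lay close together, between 0.218 and 0.264. At day 90 alone its highest value was with May, at 0.209, and that with December was 0.043. Of the probes highest in November, 75.2% were higher in short days, as were 67.6% of those highest in October and 40.3% of those highest in December, against 30.0% of all probes placed by date. Of the probes highest in June 2013, 72.6% were lower in short days, as were 53.8% of those highest in June 2014, against 33.4% of all. At 15 °C, 75.7% of the probes highest in August 2013 were lower, 29.9% of those highest in June 2013 and 45.9% of those highest in June 2014, against 28.9% of all.

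**Figure D4:**
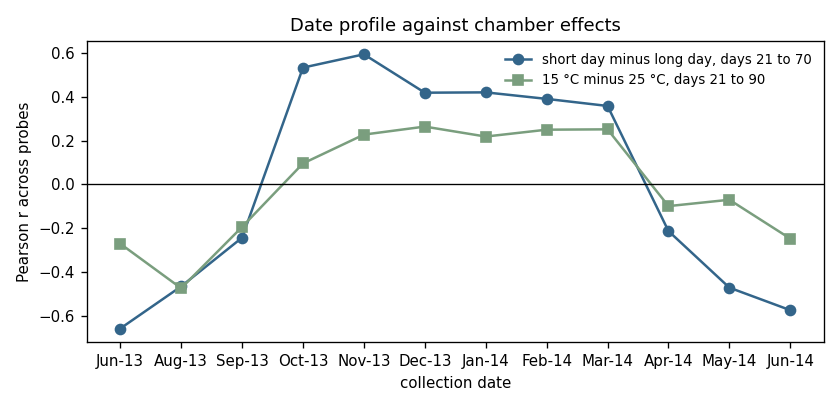
Pearson correlation across 18526 probes between the profile of each collection date and the mean short-day effect (circles) or the mean 15 °C effect (squares). The short-day values reach 0.593 in November and the 15 °C values reach -0.474 in August.

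The constant arms changed as well. Averaged over days 21 to 70, long-day shoots differed from day 0 in 1839 probes, 1078 of them higher, and averaged over days 21 to 90, shoots at 25 °C differed from day 0 in 1666, 899 of them higher. The long-day count was 99 and 191 without replicates 1 and 2 of day 0, 1136 without replicate 2 of long days at day 35, 848 with slide as a block and 248 with slide as a block and spike-in scaling together. The 25 °C count was 126 and 883 without replicates 1 and 2 of day 0, 890 without replicate 1 of day 21, 1016 and 1069 without replicates 1 and 2 of day 42, 1016 without replicate 1 of day 63, and 180 with slide as a block and spike-in scaling together. The change from day 0 to day 70 in long days correlated across probes with the change from day 0 to day 90 at 25 °C at r = 0.803, with no shared library. Of the called probes, 2106 were higher in both against 700 expected and 1615 were lower in both against 433 expected. The winter index moved with it, from -1.26 ± 0.18 (SD, n = 2) at day 0 to -0.59 ± 0.15 at day 70 in long days, and from -1.35 ± 0.03 at day 0 to -0.65 ± 0.07 at day 90 at 25 °C.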

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

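The test of brightness against the slopes of the annual libraries was chosen only after the short-day result was seen, as were the brightness covariate and the E1A spike-in scaling. The difference of the short-day effect between days 49 and 70 and day 7 passed its test in 3507 probes, and in 1144 with brightness as a covariate. Day 7 lay on slides 9 and 15 and days 49 and 70 on slides 8 and 10. Each of these slides held both arms, but an influence of slide on the effect itself was not separated from time. Without that covariate, the same test of the 15 °C effect, at days 63 and 90 against day 7, passed in 1 probe in limma, with 2265 at an unadjusted p under 0.05. Whether the treatments differ in this respect was not tested. In the negative control probes, which no comparison uses, 14 of 25 were well above background in replicate 3 of January 2014, and the next highest library had 2.

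The short-day difference came with dimmer arrays, at -0.703 log2 for the 75th percentile. The tables argue against a difference between slides, since the short-day effects measured within slide 8 and within slide 10, from days 35 to 70, correlated at 0.933 across probes, although the other 5 pairs of slides, with slides 9 and 15 that held days 7 and 21, gave 0.259, 0.349, 0.417, 0.611 and 0.668. Brightness itself stays open. The brightness slope of each probe, estimated from pairs of libraries of 1 group in experiment 1, correlated with the short-day effect at -0.359 (-0.409 to -0.161 without each pair), in the direction that brightness would give but short of the bound of 0.5 set beforehand, whereas slopes from annual libraries of 1 date gave -0.0519 (-0.148 to -0.00294), which argues against brightness but comes from another extraction protocol. With brightness as a covariate, the effects correlated with the uncorrected ones at 0.904, 95.3% of the 10635 probes called in short days kept their sign and 3967 were called with the same sign, so part of the difference may not depend on brightness, and a biological lowering of total transcript per input RNA was not tested.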

How the results depend on the processing

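The alternatives with array brightness, E1A spike-ins and without dim libraries were chosen only after the results were seen. Across all alternatives 1182 counts stayed within 1.5 times their main value and 202 did not, and the 448 values of named probes kept their direction and call. The named probes were chosen among called probes for the largest changes in a steady direction, so their values could hardly have done otherwise. Of the correlations, 135 stayed within their jackknife error and 1 did not. Most of these are the values with each of 58 libraries left out, from which that error was computed, so they could hardly leave it. The deposited values, no filter, the filter on 50% of arrays, no block, January against August alone and the mean over all days moved no count that answers a comparison by over 1.5 times. A minimum fold lowers counts by construction, and the cause of the other changes, including rises with fewer libraries, was not tested.

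The June count, 15, was 27 with quantile normalization, 59 with normexp, 46 with brightness as a covariate, 48 without the 7 dim libraries, and 0 with a slide block, alone or with spike-in scaling, and without replicate 3 at every date. The 15 °C change with time, 1, was 0 with quantile normalization, normexp, the replicate block, the slide block and brightness. Long days against day 0, 1839, was 848 with the slide block. The largest interval count, 5727, was 8607 without the dim libraries. The median of all winter differences was 0.19 log2 with quantile normalization and 0.14 with normexp, against 0.06.

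With brightness as a covariate, 2068 probes were higher and 2153 lower in short days, 3905 responded at day 70, 1144 changed with time, and the winter and short-day responses correlated at 0.441. With spike-in scaling and a slide block, the annual counts were 6080 for any date, 3676 lower in winter and 2572 for the largest interval. In experiment 1 they were 605 higher, 16244 lower, 105 at day 7, 12859 at day 70, 8411 for the change with time and 248 for long days against day 0. In experiment 2 they were 4015 lower, 1533 at day 7, 4798 at day 90 and 180 for 25 °C against day 0.

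A minimum fold of 2 left 3374 higher and 4071 lower in winter and 3383 for the largest interval. It left 821 higher and 1253 lower in short days, 271 at day 7, 2950 at day 70, 1586 for the change with time and 359 for long days against day 0. At 15 °C it left 672 higher and 351 lower, 603 at day 7, 1739 at day 90 and 230 for 25 °C against day 0.

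Leaving out single libraries gave 0 to 38 probes for June. In experiment 1 it gave 143 to 604 at day 7, 4837 to 7981 at day 70, 1356 to 3885 for the change with time and 99 to 2300 for long days against day 0. In experiment 2 it gave 1694 to 3510 at day 7, 4707 to 7963 at day 90, 0 to 81 for the change with time and 126 to 2129 for 25 °C against day 0.

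Residuals of libraries with 1 replicate number correlated at a mean of 0.058, 0.049 and -0.007, with values as low as -0.621, so the numbers gave no sign of shared plants. For libraries with 1 title code the means were -0.002, 0.149 and 0.065, against 0.002, -0.014 and -0.004 between codes. For libraries on 1 slide they were 0.166, 0.048 and 0.094, against -0.022, -0.016 and -0.034 between slides. In the annual series, number 3 marks the libraries deposited and scanned later. A replicate block gave 7325 higher and 6849 lower in winter, 6114 higher and 5622 lower in short days, and 5360 higher and 6000 lower at 15 °C. Signal near background limits the folds of the most changed probes. Averaging several probes of a gene and other gene list methods were not run, because the probes have no gene names.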

Other observations

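The classes of probe names, the spike-in and brightness alternatives, the comparison of the constant arms, its brightness tests, its tests against time and the groupings of title codes were chosen only after the data were seen. Probe names carry a field of 4 positions that can hold the letters M, L, S or W, whose meaning the files do not state. Probes with S were higher in winter in 45.4% of cases against 31.6% of the other probes (Fisher's exact test, odds ratio 1.80, adjusted p = 1.52e-81 over 60 tests), in 37.1% against 21.1% at 15 °C (odds ratio 2.20) and in 34.9% against 26.3% in short days (odds ratio 1.51). The winter odds ratio was also above 1 for probes with W (1.51), all letters (1.41), M (1.16) and L (1.13), and was 0.639 for no letter. For a letter alone it was 1.32 for S, 0.949 for W, 0.716 for M and 0.556 for L. Classes overlap, and the part of each letter was not separated. Probes with M alone were lower in winter in 51.2% of cases against 34.1% (odds ratio 2.03) and lower in short days in 40.4% against 27.2% (odds ratio 1.81), while at 15 °C 29.7% were lower against 30.6% (odds ratio 0.956, adjusted p = 0.761). Probes with L alone were highest in October or November in 19.0% of cases among those that varied over the year, and probes with M alone in 5.96%. Several probes can come from related sequences, so these p-values overstate the evidence. Directions in short days are relative to the array's 75th percentile, and relative to the E1A spike-ins 16244 probes were lower.

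The 2 constant arms changed alike, with r = 0.803 between long days at day 70 and 25 °C at day 90, each against its own day 0. The tables argue against a difference between slides, since the change within slide 10 of experiment 1 correlated with the changes within slides 12 and 14 of experiment 2 at 0.723 and 0.802, although each of these changes is 1 library minus 1 library. They also argue against array brightness, which changed by 0.10 log2 in long days and by -0.03 at 25 °C. With brightness as a covariate in both experiments the changes correlated at 0.806 (0.746 to 0.815 without each library). The covariate hardly altered the changes, which correlated with the unadjusted ones at 0.997 and 0.9998, so this r adds little to the small changes in brightness. The comparison with brightness slopes of the annual libraries, at 0.154 (0.070 to 0.206), decided nothing by itself. A candidate explanation is a change that proceeds with time after transfer: scored along the change in experiment 2, the 8 long-day libraries of days 7 to 49, which took no part in that r, followed the day at Spearman rho = 0.878 (two-sided exact permutation p = 0.0103) and Pearson r = 0.852 (p = 0.00476, and r = 0.823 without the 2 of day 7), and the score rose with day within each of their 3 title codes (one-sided exact permutation within codes p = 0.0104, the smallest that 96 arrangements allow). Plant age, calendar season and chamber conditions move together with that time and were not separated. Slide did so in part, with day 7 on slides 9 and 15 and days 35 and 49 on slides 8 and 10, and the permutations ignored it. Within slide 10 the scores at days 21, 35 and 49 were -6.13, -16.2 and 38.2. Within slide 8 the score went from 2.47 at day 35 to 16.3 at day 49, and within slide 15 from -29.5 at day 7 to -19.7 at day 21.

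Other groupings of the libraries were tried for the 4 main counts, each with limma without a block and with 100 groupings, the real one included. For any date, the real grouping gave 14979 probes and the highest other 10. For winter against summer it gave 13585 and 2. For short against long days it gave 11238, and the highest other was 9222, in a grouping with 14 of 16 libraries in their real arm. For 15 °C against 25 °C it gave 11133, and the highest other was 5977, also with 14 of 16 in their real arm. Only the real grouping, 1 of 100 in each case, reached its count. These groupings move single libraries, although title codes recur within the arms of the chambers. With the libraries of a code kept together, only the real grouping reached its count, 1 of 35 for short days and 1 of 100 for 15 °C. The highest others were 8909, with 6 of 8 codes in their real arm, and 7054, with 8 of 10. A chance division of the title codes between the arms is thus unlikely to have given the chamber counts, at a share of 0.05. For short days 1 of 35 is the smallest share possible. Every code lay in 1 arm, so these groupings cannot separate the treatment from anything else that differed between the arms. For the annual counts a chance division was tested only with single libraries as the units. No grouping kept the libraries of a date together, so the groupings do not show that winter and summer differ beyond the spread between dates.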
